A study of Mus musculus with 24 samples.

How the data were processed

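Liver RNA was measured in 24 libraries from C57BL/6J mice, 3 per group in 8 groups. The groups cross 4 genotypes with 2 diets, chow and a high fat diet, each given for 16 weeks. The control genotype carried the Alb-Cre transgene, which drives recombination in hepatocytes, and the others also carried conditional alleles of Mapk8 (the gene of JNK1), of Mapk9 (the gene of JNK2) or of both, called Jnk1, Jnk2 and Jnk1Jnk2 here. Samples were placed in groups by their titles. The labels do not say that replicates are separate mice, so p-values measure the spread between these samples, which may be technical.

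Per the labels' protocols, RNA was extracted with RNeasy columns. Per the submitters' processing notes, reads were processed with TopHat, Cufflinks and Cuffdiff on mm10, and versions were not given in the sources used here. The deposited values are FPKM (fragments scaled to transcript length and to the mapped total), which the authors made per library for 31027 Cufflinks loci with gene names, and 571 loci carry several names. Every column of values belonged to a labelled sample. Locus starts equalled the RefSeq start less 1 at 11035 of the 20250 loci matched to a RefSeq gene, so starts were read as counted from 0 and are written counted from 1.

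FPKM are not counts, so no count model was fitted. Relative depth was read from the smallest steps between low FPKM values of the same loci, which stand for 1 fragment. It ranged from 0.3 to 1 of the deepest library, chow control replicate 1. The absolute depth is unknown, so no interval for counting error is given. Some zeros were failed estimates: at 6 loci with a median of at least 10 FPKM and a span of at least 500 bases, 18 library values were 0, among them 4 libraries at Alb, the albumin gene. Those loci are not reported as changes, and an exact 0 is reported only as listed at 0.

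The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1) in 1 fit of all 24 libraries with a mean per group, 16 residual degrees of freedom and a median prior of 3.4. Of 19796 loci with any FPKM above 0, the 10562 with a mean of at least 1 FPKM were tested, and 248 of them carry several names. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 within each of 15 contrasts: each knockout against control on each diet, high fat against chow in each genotype, the interaction of diet with each knockout, and the departure of the Jnk1Jnk2 effect from the sum of both single effects on each diet. Changes are differences of log2(FPKM + 1) ± SE, which understate the change of low genes. Levels are mean FPKM ± SD. An exact test of 3 libraries against 3 cannot give a two-sided p under 0.1, so no exact test of single genes was used.

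Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 27 lists with at least 3 measured members of 28 written. An estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. Of 113 list calls over the contrasts, 4 held with an estimated correlation and 71 with fry. The 28 lists, the main tests, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule takes Mapk8, Mapk9, Mapk10, Fgf21 and Ppara in every knockout contrast, and in each contrast the called genes with the 10 largest rises and 10 largest falls whose replicates do not overlap, up to 4 called members per list, and the 5 smallest p-values where fewer than 5 loci were called. Not every gene that the rule names is printed, and those printed were picked from them after their values were seen, mostly genes whose call held with each library left out in turn. Mapk10 had a mean under 1 FPKM and was not tested. Some genes that the rule names are not reported here.

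Transcript lengths and GC content came from GENCODE vM21 models matched by name, and 9974 tested loci (94.4%) had one. Removing the length trend meant subtracting from each library the loess trend (span 0.5) of its deviation from the mean over libraries on log2 length. The settings fixed beforehand were other pseudocounts, filters and scalings, array weights, the replicate number as a block, a fit of only the groups compared, and each library left out in turn. The removal of length and GC trends, the exclusion of failed zeros and a clock score as covariate, the first component of the circadian list (53.7% of its variance), were added after seeing the data. Median-of-ratios size factors ranged from 0.907 to 1.087. Splits with size factors and quantile normalization are given where either moved the share of higher calls by over 10 percentage points or turned the balance. Comparisons that share control libraries were set beside 100 simulations of unchanged groups against those controls. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

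The method was tested on simulated data for the high fat Jnk1Jnk2 contrast over 10562 loci. Of 50 loci changed by 0.5 on the log2 scale, 54% were called, of 50 changed by 1, 96%, and all of those changed by 2 or 3. A further 10 unchanged loci were called, 5.4% of the calls. That 0 of 100 random lists passed is no test of lists of correlated genes. With a length trend added, 3341 unchanged loci were called, and after its removal 9 of 9974 with a length.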

Results

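Liver RNA-seq was made from mice whose hepatocytes lacked JNK1, JNK2 or both, the stress-activated kinases encoded by Mapk8 and Mapk9, and from mice with Alb-Cre alone, after 16 weeks on chow or on a high fat diet. Each of the 8 groups had 3 libraries. The sum of FPKM per library ranged from 634849 to 873399, and relative depth differed by up to 3.33 times between libraries. Pearson correlations of log2(FPKM + 1) within a group ranged from 0.9487 to 0.9775 and reached 0.9763 between groups, and 0 library pairs held equal values at most of the tested loci (over 50%). The first principal component held 21.5% of the variance. The 3 high fat Jnk1Jnk2 libraries had the highest sums, 849038, 873399 and 852069. Their FPKM also fell with transcript length: the Spearman correlation across genes of their deviation with length was -0.61, -0.66 and -0.6, against -0.25 to 0.42 in the other 21 libraries. Log2 changes below are given ± SE with 3 libraries per group, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

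Mapk8 (chromosome 14, 33377899 to 33447158, mm10) was lower in all libraries of the groups labelled as lacking JNK1. On chow its level was 5.19 ± 0.521 FPKM (SD, n = 3) in control, 1.93 ± 0.0497 in Jnk1, 5.2 ± 0.0264 in Jnk2 and 2.12 ± 0.305 in Jnk1Jnk2. On high fat it was 4.29 ± 0.237 in control, 1.88 ± 0.0429 in Jnk1, 4.06 ± 0.736 in Jnk2 and 1.12 ± 0.334 in Jnk1Jnk2. Per library, Mapk8 was 1.94, 1.88 and 1.98 FPKM in chow Jnk1 and 1.99, 1.9 and 2.47 in chow Jnk1Jnk2. It was 1.92, 1.84 and 1.87 in high fat Jnk1, and 1.03, 0.845 and 1.49 in high fat Jnk1Jnk2, against 3.38 to 5.77 in the other libraries. Values were per locus, so they include reads from outside any deleted part and from cells without the transgene.

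Mapk9 (chromosome 11, 49846751 to 49886421, mm10) was lower in all libraries of the groups labelled as lacking JNK2. Its level on chow was 9.94 ± 0.805 FPKM (SD, n = 3) in control, 9.87 ± 0.771 in Jnk1, 6.36 ± 0.674 in Jnk2 and 6.37 ± 0.294 in Jnk1Jnk2. On high fat it was, in the same order, 11.0 ± 0.765, 11.5 ± 0.428, 7.27 ± 0.622 and 4.62 ± 0.256. Per library, Mapk9 was 6.89, 6.59 and 5.6 FPKM in chow Jnk2 and 6.61, 6.04 and 6.46 in chow Jnk1Jnk2. It was 7.44, 6.58 and 7.79 in high fat Jnk2, and 4.81, 4.33 and 4.73 in high fat Jnk1Jnk2, against 9.01 to 12.0 in the other libraries. The targeted genes therefore went with the labels in all 24 libraries.

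**Figure D1:**
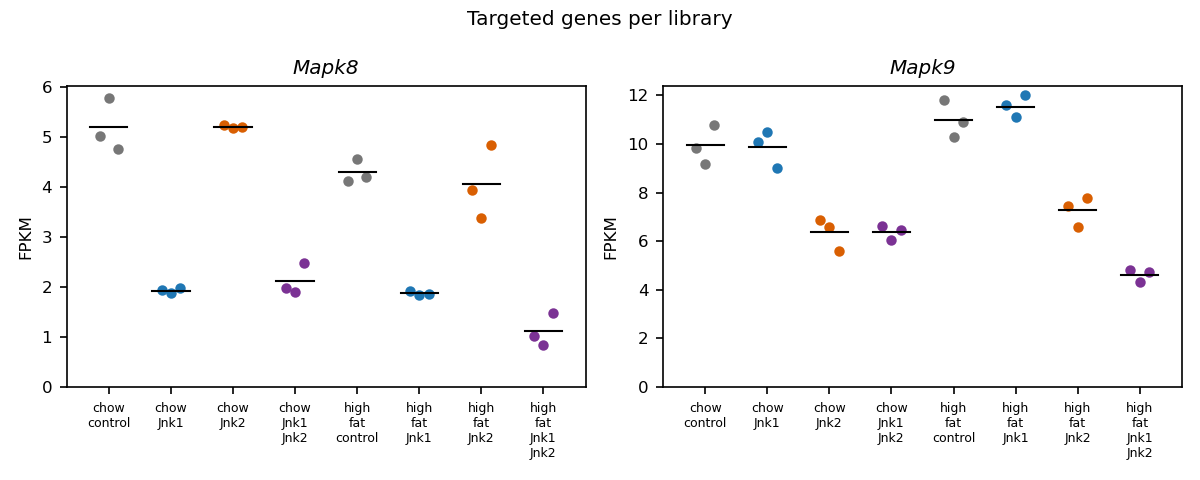
FPKM of Mapk8 and Mapk9 (linear axes) in each of the 24 libraries by diet and genotype; points are libraries and bars are group means. Mapk8 was 0.845 to 2.47 FPKM in the 12 libraries labelled as lacking JNK1 and 3.38 or more in the others, and Mapk9 was 7.79 or less in those labelled as lacking JNK2 and 9.01 or more in the others.

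On chow, 17 loci were called between livers lacking both kinases and control, and 447 with array weights. Mapk8 fell by 0.99 ± 0.11 on the log2 scale (adjusted p = 4.02e-05) and Mapk9 by 0.57 ± 0.08 (adjusted p = 0.00189). Jund, a JNK-regulated AP-1 transcription factor gene, fell by 1.09 ± 0.16 (adjusted p = 0.00143), from 48.7 ± 6.49 to 22.2 ± 1.97 FPKM. Fam25c fell by 3.59 ± 0.32 (adjusted p = 1.37e-06) and Pttg1, the securin gene of the cell cycle, by 3.43 ± 0.18 (adjusted p = 3.18e-10), each located near a targeted gene. Erdr1, in a region that the X and Y chromosomes share, was at 94.6, 76.6 and 211 FPKM in control and 13.3, 0.381 and 25.8 in Jnk1Jnk2, a fall of 3.85 ± 0.73 (adjusted p = 0.0295). Without chow control replicates 1, 2 and 3 Erdr1 had adjusted p = 0.0906, 0.057 and 0.187, without chow Jnk1Jnk2 replicates 1 and 2 0.0538 and 0.06, and with size factors 0.0519. Its change was -2.57 and -4.71 without chow Jnk1Jnk2 replicates 2 and 3. It had 0.0694 and 0.0782 with pseudocounts 0.1 and 0.01, 0.0679 with no filter and 0.058 with quantile normalization. Hist1h2ba, a histone H2B gene, was listed at 0, 0.387 and 0 FPKM in the control libraries and at 14.5, 13.3 and 20.0 in Jnk1Jnk2 (adjusted p = 2.48e-07). Fgf21, a liver hormone gene controlled by PPARα, changed by 0.08 ± 0.44 (adjusted p = 0.972) and Ppara by 0.15 ± 0.11 (adjusted p = 0.597).

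Of 10562 loci tested, 17 were called on chow between Jnk1Jnk2 and control, 3 higher and 14 lower, and 1334 had an unadjusted p under 0.05. The count was 11 without chow control replicate 1, 10 without chow control replicate 3, 9 without chow Jnk1Jnk2 replicate 1 and 11 without chow Jnk1Jnk2 replicate 2. With size factors the split was 3 higher and 9 lower, with quantile normalization 4 and 8, and with array weights 43 and 404. The AP-1 and immediate early list was lower (camera adjusted p = 0.0245, adjusted p = 0.767 with an estimated correlation), with 0 members higher, Jund alone lower and 14 not called, or 2 lower adjusted over the list alone, and had adjusted p = 0.47 without chow control replicate 1 and 0.249 without chow Jnk1Jnk2 replicate 3. The list of PPARα targets and fatty acid oxidation passed as higher with 0 of 45 members called, 1 adjusted over the list alone, and a median of 0.017 (adjusted p = 0.0242, adjusted p = 0.767 with an estimated correlation), and had adjusted p = 0.54 with quantile normalization, 0.0975 with no filter and 0.111 without chow Jnk1Jnk2 replicate 2. The stellate cell, cytochrome P450 and circadian lists passed with 0 members called, over all genes and adjusted over the list alone (adjusted p = 0.767 with an estimated correlation), and did not pass with size factors (adjusted p = 0.0607, 0.0905 and 0.15), quantile normalization, no filter or the length trend removed. Without chow Jnk1Jnk2 replicate 2 they had 0.408, 0.0674 and 0.271, and without chow control replicate 1 the stellate list had 0.101. Without chow control replicates 2 and 3 and chow Jnk1Jnk2 replicate 3 the P450 list had 0.0548, 0.122 and 0.0842 and the circadian list 0.091, 0.392 and 0.283. A fit of only the 2 groups called 7 loci and gave adjusted p = 0.0674 for Mapk8 and Jund and 0.115 for Mapk9. Jund had adjusted p = 0.23 with length and GC trends removed.

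On the high fat diet, livers lacking both kinases had higher PPARα target and macrophage lists, which had adjusted p = 0.687 and 0.79 with an estimated correlation. Single genes of lipid droplets, lipogenesis and bile acid handling changed as well. Cidec, which encodes a lipid droplet protein, rose from 7.96 ± 5.69 to 59.0 ± 4.88 FPKM (SD, n = 3), by 2.92 ± 0.37 on the log2 scale (adjusted p = 5.49e-06). Acot1, a peroxisome proliferator-induced acyl-CoA thioesterase gene, rose by 1.79 ± 0.19 (adjusted p = 1.17e-06), and Fgf21 rose by 2.08 ± 0.44 (adjusted p = 0.000692), from 10.7 ± 4.56 to 46.2 ± 7.42 FPKM. Fasn, the fatty acid synthase gene, fell by 1.58 ± 0.18 (adjusted p = 1.6e-06), Scd1, a desaturase gene, by 3.56 ± 0.73 (adjusted p = 0.000505), at -2.92 and -4.19 without high fat Jnk1Jnk2 replicates 1 and 3, and Srebf1, a regulator of lipogenesis, by 1.7 ± 0.3 (adjusted p = 0.000151). Gpnmb, a gene of lipid-laden macrophages, rose by 2.84 ± 0.57 (adjusted p = 0.000424), although 1 of its 3 Jnk1Jnk2 libraries was at 0.949 FPKM and the others at 19.3 and 20.0. Without that library, replicate 1, it rose by 3.97.

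The list of PPARα targets and fatty acid oxidation held 33 higher, 2 lower and 10 uncalled members on high fat, the same counts adjusted over the list alone (camera adjusted p = 1.98e-10, adjusted p = 0.687 with an estimated correlation). Cyp4a14 and Cyp4a31, fatty acid hydroxylase genes, rose by 1.37 ± 0.34 (adjusted p = 0.00254) and 1.61 ± 0.36 (adjusted p = 0.00104). They and Acot1 have near-identical copies, so their values are uncertain where reads could be split. Ppara itself was among the 2 that fell, by 0.69 ± 0.11 (adjusted p = 5.47e-05). Macrophage and Kupffer cell markers held 18 higher, 1 lower and 6 uncalled members, the same adjusted over the list alone (adjusted p = 4.53e-05, adjusted p = 0.79 with an estimated correlation). Among them Trem2 rose by 1.8 ± 0.36 (adjusted p = 0.000409) and Lgals3, the galectin 3 gene, by 1.93 ± 0.34 (adjusted p = 0.00015). High fat Jnk1Jnk2 replicate 1 was the lowest of its group at 16 of the 25 members, with Trem2 at 2.95 FPKM against 12.4 and 15.7 and Lgals3 at 9.79 against 32.8 and 41.0. Without it Trem2 rose by 2.45 and Lgals3 by 2.53, and the list had 17 higher and 1 lower (adjusted p = 2.01e-05, adjusted p = 0.62 with an estimated correlation). With the length trend removed, 8 macrophage markers were higher and 0 lower (adjusted p = 0.0143), and the PPARα list had adjusted p = 4.23e-12.

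The lipogenesis and lipid droplet lists did not pass (adjusted p = 0.0584 for both). The lipogenesis list passed as lower with the length trend removed (adjusted p = 0.0195, adjusted p = 0.422 with an estimated correlation), with quantile normalization (0.00348) and with no filter (0.00582), and the lipid droplet list with no filter (0.0222). With the length trend removed, the bile acid, acute phase and unfolded protein lists passed as lower (adjusted p = 0.0177, 0.000381 and 0.00335; adjusted p = 0.422, 0.422 and 0.558 with an estimated correlation). The stellate cell and endothelial lists then passed as higher (adjusted p = 0.000381 and 0.00131; adjusted p = 0.451 and 0.382 with an estimated correlation). None of these 5 passed as deposited, at adjusted p = 0.244, 0.151, 0.186, 0.0584 and 0.337 in this order. With quantile normalization the first 4 passed, at adjusted p = 0.00277, 0.0041, 0.00837 and 0.0213. Among single genes, Apoa4, an apolipoprotein gene, rose by 2.94 ± 0.41 (adjusted p = 1.35e-05), and G0s2, an inhibitor of lipolysis, by 1.76 ± 0.32 (adjusted p = 0.000184). Abcb11, the bile salt export pump gene, fell by 1.39 ± 0.1 (adjusted p = 3.98e-08), Abcc2, a canalicular transporter gene, by 1.72 ± 0.22 (adjusted p = 5.13e-06) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.66 ± 0.34 (adjusted p = 0.000511). Insr, the insulin receptor gene, fell by 1.41 ± 0.15 (adjusted p = 1.05e-06) and Igfbp2 rose by 2.13 ± 0.3 (adjusted p = 1.62e-05). The endoplasmic reticulum chaperone genes Hspa5 and Hyou1 fell by 1.16 ± 0.16 (adjusted p = 1.28e-05) and 1.24 ± 0.22 (adjusted p = 0.000168). Krt23 rose by 1.99 ± 0.3 (adjusted p = 2.51e-05).

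On high fat 5410 of 10562 loci were called between Jnk1Jnk2 and control, 2072 higher and 3338 lower. With size factors the split was 2783 higher and 2815 lower, and with quantile normalization 2489 and 2619. The changes went with transcript length: in the shortest 10% of loci the median change was 0.491 and in the longest -0.588, and across loci the Spearman correlation with length was -0.65. With the length trend removed 3298 loci were called, 1660 higher and 1638 lower, and 2359 of them were among the 5410 with the same direction. All genes named here for this comparison stayed called with the trend removed, with Fasn at -0.91, Abcc2 at -1.13, Insr at -0.76 and Fgf21 at 1.63. Mapk8 fell by 1.33 ± 0.11 (adjusted p = 9.93e-08) and Mapk9 by 1.1 ± 0.08 (adjusted p = 4.62e-08), or to -0.87 and -0.74 with the trend removed.

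**Figure D2:**
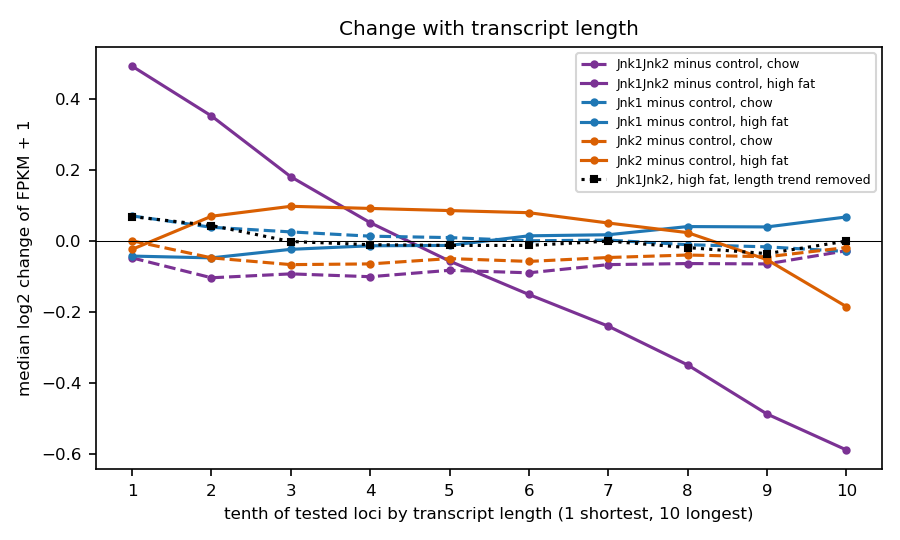
Median change of log2(FPKM + 1), knockout minus control, in 10 equal groups of the tested loci by transcript length, 1 the shortest and 10 the longest; each line is 1 contrast and the dotted line is high fat Jnk1Jnk2 after the length trend was removed. High fat Jnk1Jnk2 went from 0.491 to -0.588 and, after removal, from 0.068 to -0.001.

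Livers lacking JNK1 on chow differed from control in output genes of the circadian clock, and collection times were not given in the sources used here. Dbp, a clock output transcription factor gene, rose by 1.96 ± 0.33 (adjusted p = 0.00359), from 9.58 ± 2.41 to 40.9 ± 13.5 FPKM (SD, n = 3). Usp2, a clock output gene, rose by 2.18 ± 0.36 (adjusted p = 0.00303) and Gm129, a clock repressor gene, by 2.28 ± 0.35 (adjusted p = 0.00171). Arntl, a core activator of the clock, fell by 1.44 ± 0.28 (adjusted p = 0.00828). Alas1, the rate-limiting enzyme of heme synthesis, rose by 1.52 ± 0.22 (adjusted p = 0.000795) and Por, the P450 reductase gene, by 0.92 ± 0.16 (adjusted p = 0.00359). Elovl3, a fatty acid elongase gene, fell by 2.13 ± 0.2 (adjusted p = 6.37e-06), Slc30a10, a manganese exporter gene, by 1.57 ± 0.12 (adjusted p = 8.37e-07) and Abcb11 by 0.91 ± 0.1 (adjusted p = 5.03e-05). Mapk8 fell by 1.07 ± 0.11 (adjusted p = 1.36e-05) and Fam25c by 3.08 ± 0.32 (adjusted p = 1.4e-05). Hist1h2ba was at 4.84, 9.26 and 12.5 FPKM in Jnk1 (adjusted p = 1.04e-05), against 0, 0.387 and 0 in control. Mapk9 changed by -0.01 ± 0.08 (adjusted p = 0.987) and Fgf21 by -0.56 ± 0.44 (adjusted p = 0.622). Ppara changed by 0.33 ± 0.11 (adjusted p = 0.137, 0.0461 without chow Jnk1 replicate 1).

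Of the circadian list, 7 members were higher, 2 lower and 9 not called on chow in Jnk1, or 13 higher and 3 lower adjusted over the list alone (camera adjusted p = 8.91e-06, adjusted p = 0.343 with an estimated correlation). With a clock score as covariate, Dbp was at 0.68 (adjusted p = 0.625), Alas1 at 0.91 (adjusted p = 0.28) and Arntl at -0.19 (adjusted p = 0.901), Usp2, Gm129 and Por had adjusted p = 0.714, 0.512 and 0.286, and 30 loci were called in all. The interferon list was lower with 2 members lower and 23 not called, the same adjusted over the list alone (adjusted p = 0.0107, adjusted p = 0.806 with an estimated correlation). The erythroid list was lower with 0 of 4 called and the skeletal muscle list higher with 0 of 11, both 0 adjusted over the list alone (adjusted p = 0.0316 and 0.00271, each 0.806 with an estimated correlation). Without chow Jnk1 replicates 2 and 3 the interferon list had adjusted p = 0.0605 and 0.234. The erythroid list had 0.0874 without chow control replicate 2 and 0.0608 and 0.0811 without chow Jnk1 replicates 1 and 2, and the skeletal muscle list 0.0994 without chow Jnk1 replicate 1. In total 232 loci were called, 104 higher and 128 lower. The count was 99, 103 and 96 without chow control replicates 1, 2 and 3, and 149 and 137 without chow Jnk1 replicates 1 and 2. It was 359 with the length trend removed and 56 in a fit of only the 2 groups, in which Alas1 and Por had adjusted p = 0.0679 and 0.0711.

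On high fat, 24 loci were called between livers lacking JNK1 and control, and 716 with array weights. Lss, the lanosterol synthase gene, rose by 0.9 ± 0.15 (adjusted p = 0.00892). Ide, the insulin-degrading enzyme gene, rose by 1.02 ± 0.12 (adjusted p = 9.32e-05), Tfrc, the transferrin receptor gene, by 0.78 ± 0.13 (adjusted p = 0.0053) and Alas1 by 1.14 ± 0.22 (adjusted p = 0.0254). Elovl3 fell by 1.24 ± 0.2 (adjusted p = 0.0053), Fam25c by 3.21 ± 0.32 (adjusted p = 1.77e-05) and Mapk8 by 0.88 ± 0.11 (adjusted p = 0.000211). Hist1h2ba was at 4.2, 10.4 and 8.61 FPKM in Jnk1 and listed at 0 in the 3 control libraries. Fgf21 changed by -0.74 ± 0.44 (adjusted p = 0.53), Mapk9 by 0.06 ± 0.08 (adjusted p = 0.833) and Ppara by 0.51 ± 0.11 (adjusted p = 0.0581). It passed with size factors, quantile normalization and array weights, at 0.0391, 0.0441 and 0.00135, and with the length trend, or length and GC trends, removed, at 0.0339 and 0.0385. Lss had adjusted p = 0.074 without high fat control replicate 1 and 0.0667 and 0.0797 without high fat Jnk1 replicates 1 and 2. Alas1 had 0.104 and 0.149 without high fat control replicates 1 and 2, and 0.0667, 0.102 and 0.101 without high fat Jnk1 replicates 1, 2 and 3. With the clock score as covariate Lss, Alas1, Tfrc and Elovl3 had adjusted p = 0.312, 0.372, 0.127 and 0.307, and with no filter Alas1 had 0.0573. In a fit of only the 2 groups Ide and Tfrc had adjusted p = 0.0679, Elovl3 0.0811, Lss 0.139 and Alas1 0.145.

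The cholesterol synthesis list was higher on high fat in Jnk1, with 2 members higher, 0 lower and 23 not called, or 16 higher adjusted over the list alone (camera adjusted p = 9.51e-15, adjusted p = 0.134 with an estimated correlation). The circadian list was higher with 0 called and 10 higher and 2 lower adjusted over the list alone (adjusted p = 7.43e-06, adjusted p = 0.134 with an estimated correlation). The interferon list was lower with 0 called and 5 lower adjusted over the list alone (adjusted p = 1.16e-07, adjusted p = 0.134 with an estimated correlation). The male-predominant list was lower with 1 called and 4 over the list alone (adjusted p = 5.46e-07, adjusted p = 0.134 with an estimated correlation). The PPARα list was higher with 0 of 45 called and 3 higher adjusted over the list alone (adjusted p = 8.17e-06, adjusted p = 0.291 with an estimated correlation), and the endothelial list with 0 of 18 called and 3 over the list alone (adjusted p = 1.85e-06, adjusted p = 0.134 with an estimated correlation). The P450 and female-predominant lists were higher with 1 called and 3 over the list alone (adjusted p = 3.1e-06 and 0.000314, adjusted p = 0.134 and 0.117 with an estimated correlation). The gluconeogenesis and lipogenesis lists were higher with 0 called and 6 and 0 over the list alone (adjusted p = 0.00388 and 0.01, adjusted p = 0.308 and 0.266 with an estimated correlation). The acute phase list was lower with 0 called and 1 over the list alone (adjusted p = 0.000281, adjusted p = 0.23 with an estimated correlation). Of the loci 24 were called, 13 higher and 11 lower, with 1253 at an unadjusted p under 0.05. The count was 13 and 15 without high fat control replicates 1 and 2, 10 without high fat Jnk1 replicate 2 and 36 without high fat control replicate 3. Without high fat control replicates 1 and 2 the splits were 6 higher and 7 lower, and 7 and 8. It was 55 with size factors, 63 with quantile normalization, 716 with array weights, 315 higher and 401 lower, 12 with the clock score as covariate, 5 higher and 7 lower, and 6 in a fit of only the 2 groups.

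On chow, Pttg1 was at 29.8 ± 3.26 FPKM (SD, n = 3) in control and at 1.19 ± 0.224 in livers lacking JNK2, lower by 3.81 ± 0.18 on the log2 scale (adjusted p = 4.51e-11). Mapk9 fell by 0.57 ± 0.08 (adjusted p = 0.00402), Slc30a10 by 0.84 ± 0.12 (adjusted p = 0.00402) and Jund by 0.92 ± 0.16 (adjusted p = 0.0109). Scara5, a ferritin receptor gene, rose by 1.66 ± 0.26 (adjusted p = 0.00668). Hist1h2ba was at 5.67, 13.8 and 10.6 FPKM in Jnk2 (adjusted p = 6.44e-06), against 0, 0.387 and 0 in control. Mapk8 changed by 0.01 ± 0.11 (adjusted p = 0.992), Fgf21 by -0.52 ± 0.44 (adjusted p = 0.661) and Ppara by 0.16 ± 0.11 (adjusted p = 0.563). Jund had adjusted p = 0.0799 without chow control replicate 1, 0.0655 without chow Jnk2 replicate 2 and 0.0825 without chow Jnk2 replicate 3, and Scara5 0.05 without chow control replicate 1. With length and GC trends removed Jund had adjusted p = 0.182, and with the clock score as covariate Mapk9 and Slc30a10 had 0.0941 and Jund 0.165.

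The circadian list was higher on chow in Jnk2 with 1 member higher and 17 not called, or 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000606, adjusted p = 0.917 with an estimated correlation). The skeletal muscle and cholesterol synthesis lists were higher with 0 members called, over all genes and adjusted over the list alone (adjusted p = 0.000606 and 0.00278; adjusted p = 0.917 with an estimated correlation). The muscle list had adjusted p = 0.22 without chow Jnk2 replicate 1, and the cholesterol list 0.535 without chow control replicate 3 and 0.0584 without chow Jnk2 replicate 3. The acute phase list was higher with 0 called and 1 higher adjusted over the list alone (adjusted p = 0.00117, adjusted p = 0.917 with an estimated correlation), and had adjusted p = 0.0778 with quantile normalization and 0.43 without chow Jnk2 replicate 1. In that library Saa1 was at 2700 FPKM, against 1260 and 246 in the others of its group, and Apcs at 225, against 100 and 69.2. With fry 0 of these 4 lists held. In total 48 loci were called, 11 higher and 37 lower, and 1390 had an unadjusted p under 0.05. The count was 6, 15 and 16 without chow control replicates 1, 2 and 3 and 27, 15 and 6 without chow Jnk2 replicates 1, 2 and 3. It was 25 with size factors, 8 higher and 17 lower, 466 with array weights, 4 with the clock score as covariate and 2 in a fit of only the 2 groups. In that fit Mapk9 had adjusted p = 0.0997, Jund 0.0807, and Slc30a10 and Hist1h2ba 0.0748.

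On high fat, livers lacking JNK2 had 36 of 45 PPARα list members and 14 of 18 endothelial markers higher and of 24 acute phase members 16 lower and 1 higher, lists with adjusted p = 0.0253 with an estimated correlation. Acot1 rose by 2.01 ± 0.19 (adjusted p = 2.87e-06), from 27.8 ± 3.96 to 116 ± 26.3 FPKM (SD, n = 3), Acot2 by 1.65 ± 0.15 (adjusted p = 2.21e-06) and Ehhadh, a peroxisomal oxidation enzyme gene, by 1.93 ± 0.35 (adjusted p = 0.00138), or 1.26 without high fat Jnk2 replicate 3. Cidec rose by 3.22 ± 0.37 (adjusted p = 2.05e-05) to 52.9, 50.1 and 146 FPKM. Saa1, the serum amyloid A gene, fell by 3.5 ± 0.81 (adjusted p = 0.00779), Orm3 by 2.12 ± 0.46 (adjusted p = 0.00536), at -1.35 without high fat Jnk2 replicate 3, and Apcs, the serum amyloid P gene, by 1.76 ± 0.27 (adjusted p = 0.000323), from 186 ± 15.4 to 54.6 ± 8.44 FPKM. Fgf21 was at 12.8, 13.6 and 68.2 FPKM against 6.29, 10.4 and 15.4 in control, a change of 1.12 ± 0.44 (adjusted p = 0.102, 0.0459 without high fat Jnk2 replicate 1 and 0.0384 with the clock score as covariate). Acot1, Acot2, Saa1 and Orm3 have near-identical copies, so their values are uncertain.

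Adjusted over the list alone, 41 members of the list of PPARα targets and fatty acid oxidation and 15 endothelial markers were higher in high fat Jnk2, and 1 acute phase member was higher and 19 lower (camera adjusted p = 3.18e-26, 5.41e-10 and 9.34e-12; adjusted p = 0.0253 with an estimated correlation). Eng, an endothelial receptor gene, rose by 0.85 ± 0.1 (adjusted p = 2.09e-05) and Oit3 by 0.99 ± 0.13 (adjusted p = 7.2e-05). Of the stellate cell and fibrosis list 10 were higher and 10 not called, or 14 adjusted over the list alone (adjusted p = 1.39e-07, adjusted p = 0.313 with an estimated correlation). Col1a1, a collagen gene, rose by 1.31 ± 0.29 (adjusted p = 0.00614) and Vim by 1.01 ± 0.2 (adjusted p = 0.00249). Of the unfolded protein list 10 were lower and 13 not called, the same adjusted over the list alone (adjusted p = 3.08e-05, adjusted p = 0.318 with an estimated correlation). Sdf2l1, a chaperone partner gene, fell by 1.62 ± 0.25 (adjusted p = 0.000369) and Hspa5 by 0.95 ± 0.16 (adjusted p = 0.000843).

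Among other high fat Jnk2 changes, Fasn fell by 1.02 ± 0.18 (adjusted p = 0.000899), Acaca, the acetyl-CoA carboxylase gene, by 0.76 ± 0.12 (adjusted p = 0.000297) and Insr by 0.64 ± 0.15 (adjusted p = 0.00842). Apoa4 rose by 2.21 ± 0.41 (adjusted p = 0.00168), or 1.57 without high fat Jnk2 replicate 3, Myc by 1.39 ± 0.24 (adjusted p = 0.0009) and Krt23 by 2.25 ± 0.3 (adjusted p = 7.27e-05). Prtn3, a proteinase gene, fell by 2.97 ± 0.44 (adjusted p = 0.000219) and Pttg1 by 3.14 ± 0.18 (adjusted p = 1.63e-09). Hist1h2ba was at 13.1, 16.0 and 16.2 FPKM and listed at 0 in the 3 controls. Mapk9 fell by 0.54 ± 0.08 (adjusted p = 0.000369), Mapk8 changed by -0.08 ± 0.11 (adjusted p = 0.693) and Ppara by 0.11 ± 0.11 (adjusted p = 0.555). In total 1311 loci were called, 787 higher and 524 lower, or 807 and 680 with size factors and 900 and 776 with quantile normalization. Without high fat control replicate 2 the balance turned, to 391 higher and 464 lower, and with array weights 2824 loci were called. A fit of only the 2 groups called 126 loci, 60 higher and 66 lower, and in it Mapk9, Cidec, Ehhadh and Fasn had adjusted p = 0.073, 0.0521, 0.138 and 0.0536. Orm3, Insr, Apoa4 and Col1a1 had 0.166, 0.111, 0.11 and 0.0794 in it, and Sdf2l1, Myc and Acaca 0.0622, 0.0579 and 0.0521. High fat Jnk2 replicate 3 stood apart from the other 2 of its group in clock genes, with Dbp at 21.81 FPKM against 57.85 and 60.5.

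**Figure D3:**
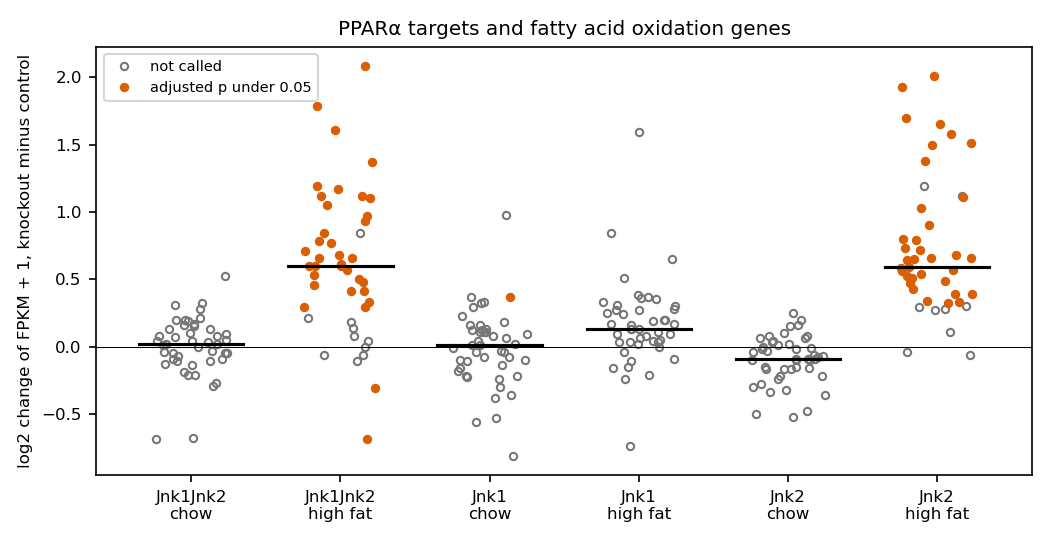
Change of log2(FPKM + 1), knockout minus control, of the 45 measured PPARα targets and fatty acid oxidation genes in each knockout contrast; filled points have an adjusted p under 0.05 and bars are medians. On high fat 33 were called higher in Jnk1Jnk2 and 36 in Jnk2, and on chow the medians lay near 0, at 0.017 in Jnk1Jnk2.

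In control livers, the high fat diet raised 23 of 25 interferon, 14 of 25 macrophage and 11 of 24 acute phase list members, and of 45 PPARα list members it lowered 13 and raised 5. With an estimated correlation adjusted p = 0.0318 for the interferon list and 0.406 for the other 3. Isg15, an interferon-induced gene, rose by 1.85 ± 0.32 (adjusted p = 0.000808), Ifit1 by 1.88 ± 0.21 (adjusted p = 1.64e-05) and Lcn2, the lipocalin 2 gene, by 3.36 ± 0.65 (adjusted p = 0.00195). Cyp2b9, a cytochrome P450 gene, rose from 0.216 ± 0.205 to 75.0 ± 6.47 FPKM (SD, n = 3), by 5.97 ± 0.65 (adjusted p = 1.37e-05), while Cyp3a11 fell by 3.45 ± 0.29 (adjusted p = 5.86e-07). Srebf1 rose by 1.67 ± 0.3 (adjusted p = 0.0011) and Cd36, a fatty acid transporter gene, by 1.47 ± 0.23 (adjusted p = 0.000347). Cyp4a14 fell by 2.3 ± 0.34 (adjusted p = 0.000196), Ehhadh by 2.13 ± 0.35 (adjusted p = 0.000475) and Acot1 by 1.72 ± 0.19 (adjusted p = 1.45e-05). The near-identical copies of Cyp4a14, Acot1 and the Ifit genes make their values uncertain.

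In the control diet comparison 24 members of the interferon list were higher adjusted over the list alone (camera adjusted p = 2.95e-21, adjusted p = 0.0318 with an estimated correlation). Adjusted over the list alone, 19 macrophage and 13 acute phase members were higher, and 5 PPARα list members higher and 17 lower (adjusted p = 6.68e-07, 4.76e-05 and 4.76e-05). For these 3 lists adjusted p = 0.406 with an estimated correlation. The gluconeogenesis and insulin list had 1 higher, 8 lower and 13 not called, or 1 and 10 adjusted over the list alone (adjusted p = 0.000425, adjusted p = 0.406 with an estimated correlation). G6pc, the glucose 6-phosphatase gene, fell by 1.39 ± 0.23 (adjusted p = 0.000548), Igfbp1 by 2.51 ± 0.54 (adjusted p = 0.00396) and Igfbp2 by 1.88 ± 0.3 (adjusted p = 0.000421). Steap4 and Saa4, of the acute phase list, rose by 2.58 ± 0.25 (adjusted p = 4.45e-06) and 2.29 ± 0.32 (adjusted p = 0.000118), and Cxcl1, a neutrophil chemokine gene, by 2.88 ± 0.42 (adjusted p = 0.000184). Dbp rose by 1.63 ± 0.33 (adjusted p = 0.00283), and with the clock score as covariate Igfbp1 had adjusted p = 0.0535.

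Between diets in control livers 1717 loci were called, 1063 higher and 654 lower on high fat, or 917 higher and 1008 lower with size factors, 951 and 1071 with quantile normalization and 989 and 1143 with the length trend removed. The count was 1127 without chow control replicate 2, 1050 without chow control replicate 3, 1106 without high fat control replicate 2, 747 with the clock score as covariate and 3067 with array weights. Mapk8 changed by -0.22 ± 0.11 (adjusted p = 0.17, 0.0253 with array weights and 0.00486 with length and GC trends removed) and Mapk9 by 0.14 ± 0.08 (adjusted p = 0.283, 0.0359 with array weights).

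In Jnk1Jnk2 livers the high fat diet raised 23 of 25 macrophage, 21 of 25 interferon and 10 of 13 lipid droplet list members, and of 21 lipogenesis members it lowered 11 and raised 1. With an estimated correlation adjusted p = 0.447 for these lists, and with the length trend removed 20, 16 and 7 were raised and 9 lowered. Trem2 rose by 2.6 ± 0.36 (adjusted p = 1.23e-05) and Gpnmb by 3.05 ± 0.57 (adjusted p = 0.000198), or 3.24 and 4.19 without high fat Jnk1Jnk2 replicate 1. Isg15 rose by 2.33 ± 0.32 (adjusted p = 1.19e-05), Cidec by 1.85 ± 0.37 (adjusted p = 0.000361) and Fgf21 by 2.09 ± 0.44 (adjusted p = 0.000556). Fasn fell by 1.4 ± 0.18 (adjusted p = 4.6e-06), Lpin1, a phosphatidate phosphatase gene, by 2.39 ± 0.45 (adjusted p = 0.000237) and Moxd1 by 3.07 ± 0.47 (adjusted p = 3.27e-05). Adjusted over the list alone, 23 macrophage, 22 interferon and 10 lipid droplet members were higher, and 1 lipogenesis member higher and 11 lower. In this order camera adjusted p = 2.99e-09, 4.33e-07, 0.024 and 0.0291. The PPARα list had 22 higher, 8 lower and 15 not called, the same adjusted over the list alone (adjusted p = 0.0291, 0.676 with an estimated correlation, 0.44 with quantile normalization), or 19 and 8 with the trend removed. Ehhadh was among those that fell, by 1.17 ± 0.35 (adjusted p = 0.00807). Of 10562 loci 6014 were called, 3179 higher and 2835 lower. The split was 3153 and 3081 with size factors, 2749 and 3024 with quantile normalization, 1925 and 2109 with the length trend removed, and 2665 and 2925 without high fat Jnk1Jnk2 replicate 3. The Spearman correlation of change with length was -0.65.

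In Jnk1 livers the diet raised 22 of 25 interferon and 8 of 25 cholesterol synthesis list members, with adjusted p = 0.0552 and 0.486 with an estimated correlation. Thrsp, a lipogenic gene, rose by 2.92 ± 0.71 (adjusted p = 0.00885) and Hmgcs1, a cholesterol synthesis gene, by 1.25 ± 0.26 (adjusted p = 0.00325). Asns, the asparagine synthetase gene, fell by 2.97 ± 0.48 (adjusted p = 0.000459) and Got1 by 2.97 ± 0.39 (adjusted p = 8.45e-05). Cyp2b9 rose by 6.65 ± 0.65 (adjusted p = 3.7e-06). The interferon list had 22 members higher and 3 not called, or 24 adjusted over the list alone (adjusted p = 1.5e-18, adjusted p = 0.0552 with an estimated correlation). The cholesterol synthesis list had 8 higher and 17 not called, or 9 over the list alone (adjusted p = 0.000822, adjusted p = 0.486 with an estimated correlation), and had adjusted p = 0.055 without high fat Jnk1 replicate 2. Of 1588 loci called, 974 were higher and 614 lower, or 847 and 912 with size factors, 905 and 908 with quantile normalization and 906 and 945 with the length trend removed. The count was 1026 without chow Jnk1 replicate 1, 986 without high fat Jnk1 replicate 1 and 945 in a fit of only the 2 groups, in which Hmgcs1 had adjusted p = 0.0808.

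In Jnk2 livers the diet raised 17 of 20 stellate cell, 19 of 25 macrophage and 29 of 45 PPARα list members, with adjusted p = 0.141, 0.232 and 0.141 with an estimated correlation. Col3a1 rose by 2.0 ± 0.25 (adjusted p = 2.62e-05), Cidec by 2.64 ± 0.37 (adjusted p = 7.82e-05), Vnn1, a PPARα target, by 1.29 ± 0.13 (adjusted p = 5.02e-06), Cd68, a macrophage marker, by 1.44 ± 0.19 (adjusted p = 4.5e-05) and Fgf21 by 1.73 ± 0.44 (adjusted p = 0.00747), or 0.97 without high fat Jnk2 replicate 3. Sqle, the squalene epoxidase gene, fell by 1.77 ± 0.42 (adjusted p = 0.00499). The PPARα list had 29 of 45 members higher and 0 lower, and the interferon list 21 of 25 higher, or 33 and 23 adjusted over the list alone (adjusted p = 4.59e-09 for both). The stellate list had 17 of 20 higher and the endothelial list 13 of 18, or 18 and 13 over the list alone (adjusted p = 4.72e-09 and 4.59e-07). The acute phase list had 1 higher and 8 lower of 24, or 1 and 9 over the list alone (adjusted p = 2.89e-05). For these 5 lists adjusted p = 0.141 with an estimated correlation. The cholesterol synthesis list had 1 higher and 10 lower of 25, or 1 and 14 adjusted over the list alone (adjusted p = 2.25e-08, adjusted p = 0.232 with an estimated correlation). Of 2751 loci called, 2076 were higher and 675 lower, or 1295 and 1201 with size factors and 1356 and 1272 with quantile normalization. The median change of all tested loci was 0.1 as deposited and -0.007 with size factors, and with size factors Col3a1 rose by 1.89, Cidec by 2.52 and Vnn1 by 1.16. The count was 1727 without chow Jnk2 replicate 3, 1791 without high fat Jnk2 replicate 1, 4570 with array weights and 1687 in a fit of only the 2 groups, in which Fgf21 had adjusted p = 0.112.

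The effect of losing both kinases differed between diets for Cidec, by 2.71 ± 0.52 (adjusted p = 0.000864), Gpnmb, by 2.85 ± 0.81 (adjusted p = 0.0106), or 3.98 without high fat Jnk1Jnk2 replicate 1, Acot1, by 1.63 ± 0.27 (adjusted p = 0.000288), and Igfbp2, by 2.28 ± 0.43 (adjusted p = 0.000694), all more positive on high fat. It was more negative on high fat for Cyp7a1, by -2.29 ± 0.48 (adjusted p = 0.00164), Fasn, by -1.65 ± 0.25 (adjusted p = 0.000146), Abcc2, by -1.84 ± 0.31 (adjusted p = 0.000294), and Ppara, by -0.84 ± 0.16 (adjusted p = 0.000656). Fgf21 was at 2.0 ± 0.62 (adjusted p = 0.0181), and at 0.0565 without chow Jnk1Jnk2 replicate 3, 0.0576 without high fat control replicate 1 and 0.111 and 0.146 with the length trend, or length and GC trends, removed. Mapk9 was at -0.53 ± 0.12 (adjusted p = 0.00258), and at -0.23 and -0.13 (adjusted p = 0.0898 and 0.391) with the same trends removed. Mapk8 was at -0.34 ± 0.15 (adjusted p = 0.0922, 0.0183 without high fat Jnk1Jnk2 replicate 3, and 0.0324 and 0.0291 with pseudocounts 0.1 and 0.01). The PPARα list had 25 members more positive, 2 more negative and 18 not called, or 30 and 2 adjusted over the list alone (adjusted p = 1.25e-06). The macrophage list had 14 more positive and 11 not called, or 17 over the list alone (adjusted p = 0.000328). The lipogenesis list had 1 more positive, 10 more negative and 10 not called, the same over the list alone (adjusted p = 0.0273). For these 3 lists adjusted p = 0.741 with an estimated correlation. In total 3689 loci were called, 1671 more positive and 2018 more negative, or 1982 and 2083 with size factors, 1665 and 1910 with quantile normalization and 1004 and 1030 with the length trend removed. Without high fat Jnk1Jnk2 replicate 1 the balance turned, to 2040 and 1884, and at a mean of at least 5 FPKM to 1413 and 1123.

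For JNK1 the interaction with diet called 0 of 10562 loci with limma, and 545 had an unadjusted p under 0.05. The count was 1 without chow control replicate 2, without high fat control replicate 2 or without high fat control replicate 3, and 1, Mir2861, in a fit of only the 4 groups (adjusted p = 2.54e-11). The smallest p-values in the fit of all libraries, none of which passed, were those of Slc30a10, at 0.84 ± 0.18, Mug-ps1, a pseudogene of a family with near-identical members, at 1.14 ± 0.24, and Fam193b, at 0.59 ± 0.13 (adjusted p = 0.516 for each), and of the Rnase4 and Ang locus, at -0.91 ± 0.2 (adjusted p = 0.521). Mir2861, of 82 bases, was listed at 795, 948 and 1110 FPKM in high fat Jnk1, at 544 in 1 chow Jnk1Jnk2 library and at 0 in the others (adjusted p = 0.516), and the fit of only the 4 groups left that library out. Mapk8, Mapk9, Fgf21 and Ppara were at 0.19 ± 0.15, 0.07 ± 0.12, -0.18 ± 0.62 and 0.18 ± 0.16 (adjusted p = 0.926, 0.976, 0.991 and 0.938). The cholesterol synthesis list passed as more positive on high fat with 0 of 25 members called, over all genes or adjusted over the list alone (camera adjusted p = 3.03e-06, adjusted p = 0.572 with an estimated correlation). So did the PPARα list with 0 of 45 called and 1 adjusted over the list alone (adjusted p = 0.00124, adjusted p = 0.572 with an estimated correlation).

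The effect of losing JNK2 differed between diets for Acot1, by 2.34 ± 0.27 (adjusted p = 0.000137), Ehhadh, by 2.23 ± 0.49 (adjusted p = 0.0105), or 1.55 without high fat Jnk2 replicate 3, Cidec, by 3.5 ± 0.52 (adjusted p = 0.000692), and Eng, by 0.9 ± 0.14 (adjusted p = 0.00098), all more positive on high fat. It was more negative for Apcs, by -2.17 ± 0.38 (adjusted p = 0.0028), Saa4, by -2.1 ± 0.45 (adjusted p = 0.00955), or -1.5 without that library, Cxcl1, by -3.07 ± 0.6 (adjusted p = 0.00549), and Steap4, by -1.97 ± 0.36 (adjusted p = 0.00366). Jund, lower on chow, was at 1.17 ± 0.22 (adjusted p = 0.00451), and at 0.55 (adjusted p = 0.207) with length and GC trends removed. Mapk8, Mapk9, Fgf21 and Ppara were at -0.08 ± 0.15, 0.03 ± 0.12, 1.64 ± 0.62 and -0.05 ± 0.16 (adjusted p = 0.772, 0.895, 0.0978 and 0.875), with Mapk9 at -0.04 with size factors and Fgf21 at adjusted p = 0.0416 with array weights. Of the PPARα list 24 members were more positive and 21 not called, or 36 adjusted over the list alone (camera adjusted p = 4.2e-18, adjusted p = 0.0671 with an estimated correlation). Of the acute phase list 13 were more negative and 11 not called, or 1 more positive and 17 more negative over the list alone (adjusted p = 2.12e-12, adjusted p = 0.0557 with an estimated correlation). Of the endothelial list 8 were more positive and 10 not called, or 11 over the list alone (adjusted p = 2.64e-06, adjusted p = 0.133 with an estimated correlation). In total 1005 loci were called, 653 more positive and 352 more negative, or 556 and 511 with size factors and 662 and 587 with quantile normalization. The count was 640 without chow control replicate 2, 631 without chow control replicate 3, 509 without chow Jnk2 replicate 3 and 569 without high fat control replicate 2. It was 2375 with array weights, 494 with the clock score as covariate and 655 in a fit of only the 4 groups, in which Ehhadh and Saa4 had adjusted p = 0.0648 and 0.0535.

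**Figure D4:**
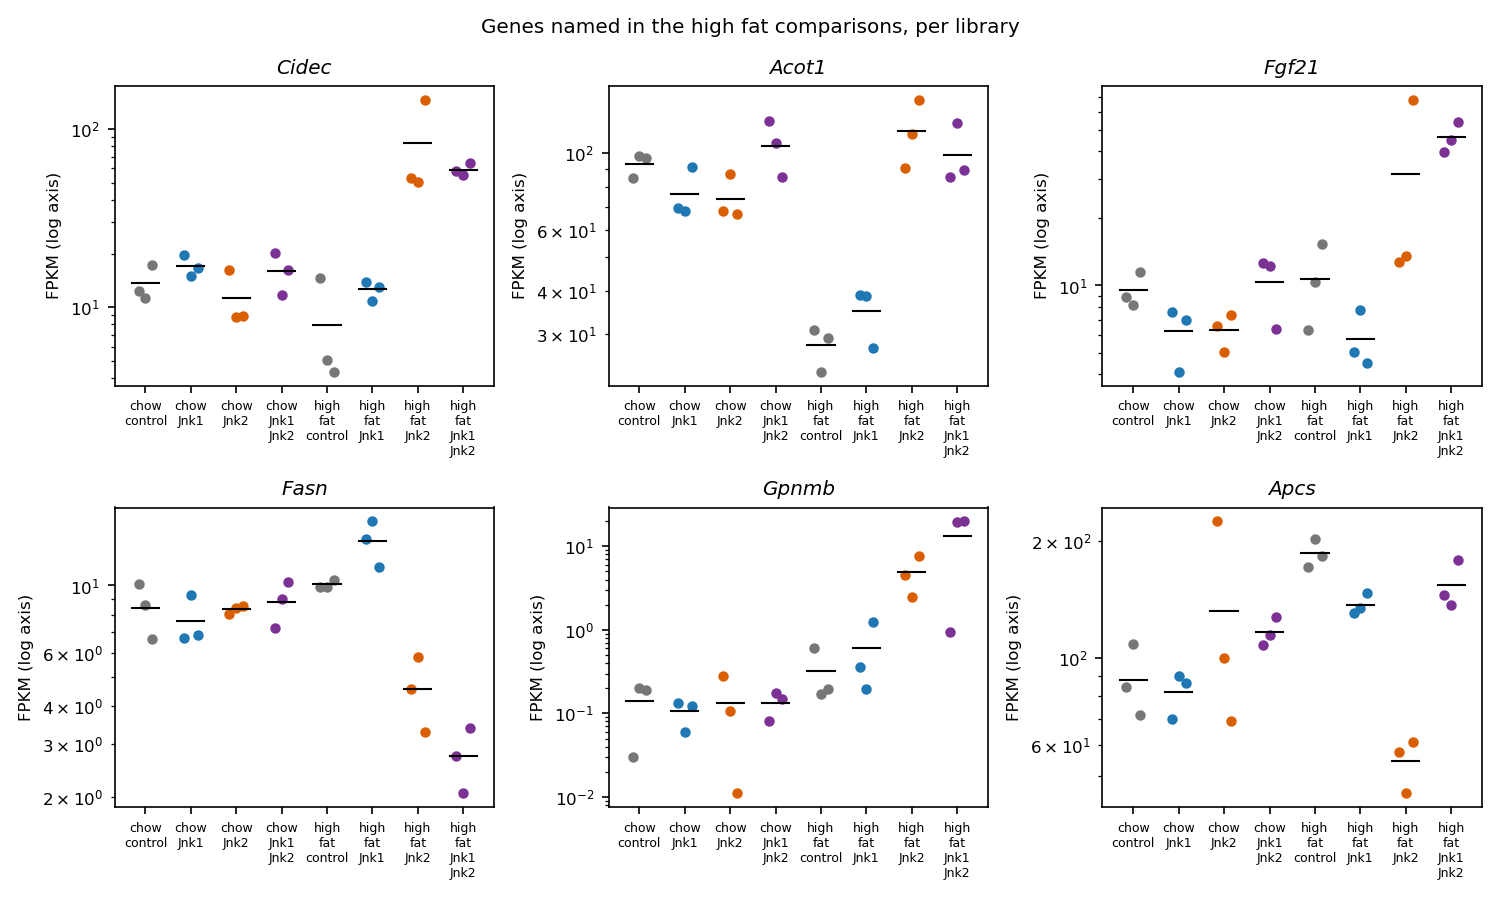
FPKM (log axes) of Cidec, Acot1, Fgf21, Fasn, Gpnmb and Apcs in each of the 24 libraries by diet and genotype; points are libraries and bars are group means. Cidec was 50.1 FPKM or more in the high fat Jnk2 and Jnk1Jnk2 libraries and 20.2 or less in all others, and Apcs was 61.1 or less in high fat Jnk2.

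On chow, the Jnk1Jnk2 effect departed from the sum of both single effects at 162 loci, among them Elovl3, Slc30a10, Alas1 and clock genes. Elovl3 was above the sum by 2.75 ± 0.28 (adjusted p = 2.97e-05) and Slc30a10 by 1.96 ± 0.18 (adjusted p = 6.87e-06). Dbp was below it by -2.64 ± 0.47 (adjusted p = 0.00716), Per3, a clock gene, by -2.19 ± 0.39 (adjusted p = 0.00701) and Alas1 by -2.07 ± 0.31 (adjusted p = 0.00221). Mapk8, Mapk9, Fgf21 and Ppara were at 0.08 ± 0.15, 0.01 ± 0.12, 1.16 ± 0.62 and -0.34 ± 0.16 (adjusted p = 0.893, 0.981, 0.429 and 0.337). Of the circadian list 2 members were above the sum, 6 below and 10 not called, or 4 and 12 adjusted over the list alone (camera adjusted p = 4.06e-05, adjusted p = 0.536 with an estimated correlation). Of the skeletal muscle list 0 of 11 were called, or 8 below adjusted over the list alone (adjusted p = 4.06e-05, adjusted p = 0.932 with an estimated correlation). With the clock score as covariate Dbp and Elovl3 were at -0.8 and 1.79 (adjusted p = 0.772 and 0.116). Per3 and Alas1 had 0.917 and 0.383, and 7 loci were called. In total 162 loci were called, 74 above and 88 below, or 123 and 105 with size factors, 138 and 95 with quantile normalization and 176 and 135 with the length trend removed. Without chow Jnk1 replicate 1 it was 71 and 67, and without chow Jnk2 replicates 1 and 2 69 and 65, and 57 and 49. The count was 90 and 94 without chow control replicates 1 and 2, 106 and 58 without chow Jnk2 replicates 2 and 3, 72 and 81 without chow Jnk1Jnk2 replicates 1 and 2, and 423 with array weights.

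On high fat, the acute phase genes Apcs and Hamp, the hepcidin gene, lay above the sum of both single effects in Jnk1Jnk2, by 1.91 ± 0.38 (adjusted p = 0.00117) and 2.42 ± 0.53 (adjusted p = 0.00235). Ppara lay below it by -1.31 ± 0.16 (adjusted p = 6.67e-05), as did Oit3, an endothelial marker, by -1.32 ± 0.18 (adjusted p = 0.000164), Cpt1a, the carnitine palmitoyltransferase gene, by -1.13 ± 0.24 (adjusted p = 0.00175) and Gpam, of glycerolipid synthesis, by -1.75 ± 0.32 (adjusted p = 0.000695). Mapk9 was at -0.62 ± 0.12 (adjusted p = 0.000994, 0.127 with the length trend and 0.0952 with length and GC trends removed). Mapk8 was at -0.37 ± 0.15 (adjusted p = 0.0622), and had 0.0212 without high fat Jnk2 replicate 2, 0.012 without high fat Jnk1Jnk2 replicate 3, 0.0284 and 0.0266 with pseudocounts 0.1 and 0.01, and 0.0346 with array weights. Fgf21 was at 1.7 ± 0.62 (adjusted p = 0.0383), and had 0.214 with the length trend and 0.198 with length and GC trends removed. It had 0.077 with no filter, 0.066 with quantile normalization, 0.113 in a fit of only the 4 groups and 0.553 with the clock score. It had adjusted p = 0.0643 to 0.11 without high fat control replicate 2 or 3, Jnk1 1 or 3, Jnk2 1 or 2, or Jnk1Jnk2 2 or 3. Without high fat Jnk2 replicate 3 it was at 2.47. With the clock score as covariate Hamp had adjusted p = 0.0531. Of the endothelial list 11 were below and 7 not called, or 13 adjusted over the list alone, and of the acute phase list 7 above and 17 not called, or 3 over the list alone (adjusted p = 0.00119 for both). Of the lipogenesis list 8 were below and 13 not called, the same over the list alone (adjusted p = 0.0237, 0.0515 without high fat Jnk1 replicate 2 and 0.0553 without high fat Jnk2 replicate 2). For these 3 lists adjusted p = 0.818 with an estimated correlation. The acute phase list had adjusted p = 0.0733 with quantile normalization. In total 3904 loci were called, 1325 above and 2579 below, or 1899 and 1988 with size factors and 1537 and 1843 with quantile normalization. With the trend removed 1851 were called. The median of all tested loci was -0.136 as deposited and -0.027 with size factors, and with size factors Apcs was at 2.05, Ppara at -1.17 and Oit3 at -1.19.

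Across genes, the Jnk1Jnk2 effects on the 2 diets had a Pearson correlation of 0.049 and a Spearman correlation of -0.064, and genes are not independent replicates. With 1 library left out the Pearson value ranged from -0.012 to 0.093, with a jackknife spread of 0.115. Of the loci called on either diet 12 were called on both, all in the same direction. They included Mapk8, Mapk9, Pttg1, Fam25c, Hist1h2ba, Timd2 and Jund, whose change was -1.09 on chow and -0.42 on high fat.

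The high fat Jnk2 and Jnk1Jnk2 comparisons used the same 3 control libraries. Of the loci called, 385 were higher in both and 438 lower in both, against 154.4 and 165.6 for independent lists, and 35 went opposite ways. Cidec, Acot1, Apoa4, Krt23, Fasn, Hspa5 and Insr were among the shared genes with the same direction. The correlation of the changes across genes was 0.55, against 0.5 in simulations of unchanged groups with those controls, and the covariance was 0.127 against 0.0446. The 3 controls could not be split into parts of 2 or more, so part of the excess may come from the shared controls. As deposited, the other high fat pairs lay below the simulations, with correlations of 0.33 for Jnk1 and Jnk2 and 0.14 for Jnk1 and Jnk1Jnk2 against 0.51, and covariances of 0.0433 against 0.0454 and 0.0276 against 0.0456. With the length trend removed the covariances were 0.0369 against 0.0333 and 0.0304 against 0.032. On chow, Jnk1 and Jnk2 shared 8 higher and 13 lower loci, against 0.1 and 0.4 for independent lists, with a correlation of 0.5 against 0.5 simulated and a covariance of 0.0543 against 0.0445.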

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

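The 15 Mb window beside the targeted genes, and most of the tests below, were chosen after seeing results. What the length test among loci that diet did not move, the omission of single libraries and the clock score would show was written down beforehand.

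Tests of the difference called 3689 loci for loss of both kinases between diets (2034 with the length trend removed) and 1005 for JNK2 (973). Against the sum of single effects in Jnk1Jnk2 they called 162 on chow (311) and 3904 on high fat (1851). Between diets the Jnk1Jnk2 effect differed by 2.71 for Cidec, 2.85 for Gpnmb, 2.38 for Apoa4, -2.29 for Cyp7a1, -1.65 for Fasn and 1.63 for Acot1. The Jnk2 effect differed by 3.5 for Cidec, 2.34 for Acot1, 2.23 for Ehhadh, -2.17 for Apcs, -2.1 for Saa4 and -3.07 for Cxcl1.

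Regroupings of the libraries were set beside the real counts. For a comparison of 3 with 3 libraries only 10 regroupings exist, of which 1, the real grouping, gave as many calls, and 10 are too few for such a test. For the effect of both kinases between diets, 4 of 100 regroupings called as many as the real 3689, the real one included, with 3948 the highest other. On high fat, 3 of 100 reached the 3904 loci outside the sum of single effects, with 4366 the highest other. Regroupings also mix libraries of groups that differ by genotype or diet, so they do not test the difference of effects alone. They cannot exclude chance for these counts. Of the 11 others that kept the 3 high fat Jnk1Jnk2 libraries together 3 called as many as 3689. Of 2 such others for the sum on high fat 1 reached 3904. With these libraries apart 3904 was reached too, but 3689 was not. For JNK2 between diets the real 1005 stood against 448 as the highest other, and for the sum on chow 162 against 14. Each was reached by 1 of 100, with the same limit. For JNK1 between diets the real count was 0, which all 100 regroupings reach whatever the data, with 48 the highest, so the comparison shows nothing.

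The high fat Jnk1Jnk2 libraries had lower values for longer transcripts. Depth as the cause was excluded, since libraries of other groups in the same depth range had a correlation with length no lower than -0.25. Among loci that diet did not move in controls the correlation of the change with length was -0.69, which is consistent with length-dependent recovery of RNA or reads in these 3 libraries. Loss of both kinases on high fat cannot be told apart from this, because it has the same 3 libraries and the lowest other value was -0.25.

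The PPARα target list was higher in high fat Jnk2 and Jnk1Jnk2, with medians of 0.586 and 0.601, and also passed in high fat Jnk1, with 0 of 45 members called and a median of 0.133 (adjusted p = 8.17e-06); in this order adjusted p = 0.0253, 0.687 and 0.291 with an estimated correlation. The length trend as the whole cause was argued against by 4.23e-12, the larger adjusted p with it removed, with 32 members called higher in Jnk1Jnk2, and a single library by 2.39e-08, the highest over the omissions, with 29 or more members called higher. With the clock score as covariate the larger adjusted p was 1.22e-10 (33 members higher in Jnk1Jnk2, 37 in Jnk2). Yet Jnk1Jnk2 scores overlapped control though Arntl was lower. Tests between diets argued against loss of JNK2 whatever the diet (1.25e-06, but 0.741 for Jnk1Jnk2 and 0.0671 for Jnk2 with an estimated correlation). So did 25 and 24 members each more positive on high fat. Loss of JNK2 on high fat (1.98e-10) and collection time or feeding stay open, and Jnk1 livers, where the list passed too, keep JNK2.

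Besides Mapk8 itself, 3 loci were called in all 4 comparisons of livers lacking JNK1, of which Gm3219 (34345055 to 34345658) and Fam25c (34351882 to 34355393) lay 0.97 Mb from Mapk8, start to start, on chromosome 14 of mm10 (Fisher's exact test p = 0.00037), although they adjoin each other and are not independent. Besides Mapk9 itself, 3 were called in livers lacking JNK2, of which Pttg1 (43420248 to 43426248) and Timd2 (46668960 to 46707104) lay near Mapk9 on chromosome 11 (Fisher's exact test p = 0.00061), but on chow Timd2 lost its call whichever library was left out, with adjusted p = 0.0569 to 0.192 in Jnk1Jnk2 and 0.0675 to 0.233 in Jnk2, with no filter in both (0.0542 and 0.0673), and in Jnk2 with size factors (0.0532) and pseudocount 0.1 (0.0502). The other, Hist1h2ba on chromosome 13, was the same locus in both and lay near neither gene. The window was set after these calls were seen and each test rests on 2 loci, so DNA carried along with the targeted alleles and a response to loss of JNK whatever the position (larger value 0.00061) both stay open.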

How the results depend on the processing

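Length and GC removal, the exclusion of failed zeros and the clock score were chosen after seeing the data. No called gene among those named, and no called list, turned direction. The cause of the changes below was not tested, except that a mean of at least 5 FPKM tested fewer loci and fits of only the groups, or with a library left out, used fewer libraries. Relative depth differed by 3.33 times between libraries, and 18 values of 0 at 6 loci were taken as failed quantification. A transcript-level alternative was not run because the values are per gene locus.

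Counts of called loci, with comparisons named by genotype and diet, changed by more than 1.5 times as follows. Array weights: Jnk1Jnk2 chow 447, Jnk1 high fat 716, Jnk2 chow 466, Jnk2 high fat 2824, diet in control 3067, diet in Jnk2 4570, diet by Jnk2 2375, sum on chow 423. Only the groups: Jnk1Jnk2 chow 7, Jnk1 chow 56, Jnk1 high fat 6, Jnk2 chow 2, Jnk2 high fat 126, diet in Jnk1 945, diet in Jnk2 1687, diet by Jnk1 1, diet by Jnk2 655. Mean FPKM of at least 5: Jnk1Jnk2 high fat 3509, Jnk1 high fat 15, diet in Jnk1Jnk2 3898, diet in Jnk2 1662. No filter: Jnk2 chow 25, sum on chow 104. Pseudocount 0.1: Jnk2 chow 31. Size factors: Jnk1 high fat 55, Jnk2 chow 25. Quantile normalization: Jnk1 high fat 63. Length trend removed: Jnk1Jnk2 high fat 3298, Jnk1 chow 359, Jnk1 high fat 38, diet by Jnk1Jnk2 2034, sum on chow 311, sum on high fat 1851. Length and GC trends removed: Jnk1Jnk2 chow 8, high fat 3275, Jnk1 chow 418, high fat 44, Jnk2 chow 24, diet by Jnk1Jnk2 1775, sum on chow 355, sum on high fat 1839. Clock score: Jnk1 chow 30, Jnk1 high fat 12, Jnk2 chow 4, diet in control 747, diet by Jnk2 494, sum on chow 7.

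With 1 library left out the counts ranged from 9 to 13 (Jnk1Jnk2 chow), 4369 to 5449 (Jnk1Jnk2 high fat), 96 to 199 (Jnk1 chow), 10 to 36 (Jnk1 high fat), 6 to 27 (Jnk2 chow), 855 to 1408 (Jnk2 high fat) and 1050 to 1619 (diet in control). They ranged from 5063 to 5901 (diet in Jnk1Jnk2), 986 to 1550 (diet in Jnk1), 1727 to 2969 (diet in Jnk2), 2831 to 3924 (diet by Jnk1Jnk2), 0 to 1 (diet by Jnk1), 509 to 1337 (diet by Jnk2), 58 to 176 (sum on chow) and 2849 to 3972 (sum on high fat). The correlation of the Jnk1Jnk2 effects on the 2 diets ranged from -0.012 to 0.093, with -0.002 without high fat control replicate 3.

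Pairing by replicate number was not seen, since in no comparison were all 3 same-number correlations over 0.1 (0.21, 0.06 and 0.03 for Jnk1Jnk2 on high fat), which cannot exclude it. Only for Jnk2 on high fat did the same-number values, 0.01 to 0.07, lie at or above all others, -0.06 to 0.01. With that number as a block, 48 loci, not 24, were called for Jnk1 on high fat, and the other counts stayed within 1.5 times. Of the 113 list calls, 4 were kept with an estimated correlation, 71 with fry, 111 with pseudocount 0.1, 108 with no filter, 105 with size factors, 99 with quantile normalization, 103 with the replicate block and 101 with the length trend removed, with 0 turned.

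Uncalled values that changed sign or became 0 follow, with the range over single libraries left out. Fgf21, Jnk1Jnk2 chow: 0 with array weights and -0.01, -0.08 and -0.06 without chow control replicate 2 and chow Jnk1Jnk2 replicates 1 and 2 (range -0.08 to 0.37). With the clock score Fgf21 was 0.88 in Jnk1 chow, 0.2 in Jnk1 high fat, 0.3 in Jnk2 chow and -0.91 for the sum on chow. For diet by Jnk1 it was 0.06 with array weights and 0.1 without high fat control replicate 3 (range -0.49 to 0.1). Mapk9, Jnk1 chow: 0.02 with array weights, 0 with length removed, 0.01 with length and GC removed, 0.16 with the clock score, 0.05 without chow control or chow Jnk1 replicate 3 (range -0.06 to 0.05). Mapk9, diet by Jnk1: -0.01 with array weights. Mapk9, diet by Jnk2: -0.04 with size factors, -0.05 with quantile normalization, array weights or the clock score, -0.01 with length removed, and -0.02, -0.04, -0.01 and -0.01 without chow control replicate 3, chow Jnk2 replicate 3, high fat control replicate 2 and high fat Jnk2 replicate 3 (range -0.04 to 0.1). Mapk9, sum on chow: 0 with array weights, -0.22 with the clock score and -0.04, -0.04, -0.06 and -0.01 without replicate 3 of chow control, Jnk1 or Jnk2 or replicate 1 of Jnk1Jnk2 (range -0.06 to 0.07). Mapk8, Jnk2 chow: -0.02 with array weights, -0.01 with length and GC removed, 0 with the clock score, -0.01 and -0.04 without chow control replicates 1 and 3 (range -0.04 to 0.07). Mapk8, Jnk2 high fat: 0.13 with length and GC removed and 0.02 without high fat Jnk2 replicate 2 (range -0.18 to 0.02). Mapk8, diet by Jnk1Jnk2: 0.07 and 0.23 with length, or length and GC, removed. Mapk8, diet by Jnk2: 0.13 with length and GC removed and 0.01 without high fat Jnk2 replicate 2 (range -0.19 to 0.01). Mapk8, sum on chow: 0 without chow Jnk1Jnk2 replicate 3 (range 0 to 0.13). Mapk8, sum on high fat: 0.08 with length removed. Ppara, diet by Jnk2: 0.03 with the clock score.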

Other observations

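The gene groups below were picked for description after seeing the results. The male-predominant list was lower on high fat in all 4 genotypes, and in none did this hold with an estimated correlation. Of 17 list members, 1 was higher and 6 lower in control (camera adjusted p = 0.0012, adjusted p = 0.406 with an estimated correlation), 1 and 12 in Jnk1Jnk2 (adjusted p = 0.0122, adjusted p = 0.461 with an estimated correlation), 1 and 8 in Jnk1 (adjusted p = 5.35e-06, adjusted p = 0.457 with an estimated correlation), and 0 and 7 in Jnk2 (adjusted p = 3.18e-07, adjusted p = 0.141 with an estimated correlation). Adjusted over the list alone these were 2 and 11, 2 and 12, 1 and 9, and 0 and 8. Moxd1, a monooxygenase-like gene, changed by -2.98 ± 0.47, -3.07 ± 0.47, -2.98 ± 0.47 and -3.39 ± 0.47 in the same order (adjusted p = 0.000362, 3.27e-05, 0.000378 and 7.64e-05), and Cyp4a12b, a male-predominant hydroxylase gene, by -3.04 ± 0.37, -2.52 ± 0.37, -3.47 ± 0.37 and -1.46 ± 0.37 (adjusted p = 3e-05, 2.08e-05, 9.26e-06 and 0.00714). Without chow Jnk1 replicate 1 Moxd1 changed by -3.76 in Jnk1. Cyp4a12b was at 4.48, 6.63 and 19.4 FPKM in high fat Jnk2.

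In high fat Jnk2 livers, other lists with fewer called members also passed. The lipid droplet list had 4 of 13 members higher, or 6 adjusted over the list alone (adjusted p = 0.00139, adjusted p = 0.258 with an estimated correlation), and the AP-1 list 3 of 15, or 4 over the list alone (adjusted p = 0.00321, adjusted p = 0.318 with an estimated correlation), with adjusted p = 0.0736 without high fat Jnk2 replicate 3. The interferon list had 4 of 25 members lower, or 6 over the list alone (adjusted p = 0.00128, adjusted p = 0.416 with an estimated correlation), with 0.0875 without high fat control replicate 2 and 0.0743 without high fat Jnk2 replicate 3. Of the macrophage list 6 of 25 were higher, the same over the list alone (adjusted p = 0.0311, adjusted p = 0.687 with an estimated correlation), and with the length trend removed it had adjusted p = 0.0686. Without high fat control replicates 1 and 3 and high fat Jnk2 replicate 3 it had 0.13, 0.129 and 0.387. Cd74, an antigen presentation gene, rose by 0.87 ± 0.17 (adjusted p = 0.00245, 0.0694 in a fit of only the 2 groups).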
